A study of Mus musculus with 6 samples.

How the data were processed

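Gene expression was profiled on 6 biotin-labelled single-colour arrays, 1 for each of 6 groups of primary mouse macrophages. Per the labels, total RNA was extracted with a spin-column kit, and 0.5 ug was reverse transcribed from an oligo-dT primer and amplified by in vitro transcription. The deposited values are in the unit intensity, on a linear scale. Every array's median lay between 0.981 and 0.987, so the values had already been scaled between arrays. The labels do not state the scaling method, and background subtraction is inferred only from 19 to 28 values per array at or below 0.

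The table held 10076 probes. Of these, 8983 carried 1 gene symbol, 1 carried several and 1092 carried none. The named probes stood for 8841 genes, and 138 genes with several probes were read from the probe with the highest mean. Gene IDs of 8975 probes were found in a mouse gene table, and 0 symbols changed through it. Each array was floored at its own 25th percentile, 0.198 to 0.245 units, and log2-transformed. A fold or log2 difference that uses a floored value is a lower bound, given as "at least". For each pair of arrays a gene was measured when the brighter array stood at or above its own median. Genes at least 2-fold apart were counted as higher or lower. This count has no test, because each group has 1 array.

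The 6 groups form 3 pairs of arrays with and without TSA, 2 pairs with and without LPS, and 2 pairs with and without GW3965. An additive model with terms for LPS, GW3965 and TSA was fitted to 5080 genes with limma 3.58.1 in R 4.3.3. It used empirical Bayes moderation with an intensity trend, 2 residual degrees of freedom and 16.9 prior degrees of freedom. A floored value enters this fit as the floor, so effects of genes under the floor on some arrays are approximate. Genes with a Benjamini-Hochberg adjusted p under 0.05, two-sided, are said to have risen or fallen. All standard errors (SE) and adjusted p-values come from this fit. Its residual also holds any dependence of one treatment on another, so genes with such a dependence pass less often. The labels do not say that the arrays came from separate cultures or animals, so the p-values measure only the spread between these arrays.

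Groups, comparisons, thresholds, 31 gene lists and the naming rule were chosen before the data were examined. The lists held 810 different symbols, some of them in several lists. Of these symbols 605 were on the array, 6 of them through a synonym. A list's median in each of 7 comparisons was set against 10000 random lists of the same size matched on mean level in 20 bins, for lists with at least 5 measured members. A percentile outside 2.5 to 97.5 is called outside the middle 95 percent. Of 217 list medians, 193 had a percentile and 64 lay outside. For lists of randomly drawn genes 5 percent would do so. Members of a fixed list can move together and the 7 comparisons reuse 6 arrays, so the count of 64 is no test against that share.

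Named genes are the 10 highest and 10 lowest with LPS, with the same direction in GW3965 + LPS; the 10 up and 10 down with the largest mean over 3 TSA pairs, each at least 2-fold; the 10 strongly LPS-induced genes with the largest drop and the 10 with the smallest difference with TSA; the 10 up and 10 down in both GW3965 pairs at 1.5-fold or more; the 4 members of each list farthest from 0; and 16 genes fixed by name. List members outside this rule are named where limma called 10 or fewer, and were chosen after their values were seen. Strong induction meant at least 4-fold with LPS and with GW3965 + LPS.

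The pipeline was tested on 20 simulated sets. Their noise was drawn for each gene alone, so they hold no variation shared by the genes of a sample. limma recovered 86% of genes changed 2-fold and 99.7% of those changed 4-fold, with 4.66% false calls. In a single pair the size rule recovered 46.5% and 96%. In sets with no effect of TSA limma called 0.15 genes for TSA on average. In separate sets with no effect of any treatment the size rule called 70.8 to 73.8 genes per comparison. Of genes read by 2 measured probes, 75% to 97.5% had probe differences within 2-fold of each other. Alternatives covered scaling (quantile normalization, cyclic loess), the floor, the level filter, probe averaging, the size threshold, the prior variance, the array on which LPS-induced genes were chosen, and leaving out a pair. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Probes with no symbol were left out of all gene comparisons and are counted at the end. The precision is limited by the number of arrays.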

Results

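Messenger RNA was measured in thioglycollate-elicited macrophages, inflammatory cells recruited by a sterile irritant, from female C57BL/6 mice aged 6 weeks. The 6 groups were No treatment, TSA, LPS, TSA + LPS, GW3965 + LPS and TSA + GW3965 + LPS, each with 1 array. TSA is trichostatin A, an inhibitor of histone deacetylases, the enzymes that take acetyl groups off histones. LPS is lipopolysaccharide, the bacterial cell wall component that Toll-like receptors sense. GW3965 is an agonist of the liver X receptors (LXR), nuclear receptors that switch on genes of cholesterol export. The labels give no dose and no time. There are no replicates, so the value of a single pair of arrays carries no error. Rank correlations between arrays, across genes that are not independent replicates, ran from 0.934 to 0.986.

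LPS against No treatment shows which genes the stimulus alone switched on. LPS-treated macrophages held far more mRNA for cytokines, chemokines and antiviral proteins. Il1b, a fever-inducing cytokine, read 674 with LPS and 0.359 without it, a 1880-fold difference. Il6, a cytokine of the acute phase response, was 436-fold higher, and the interferon-induced chemokine Cxcl10 was 292-fold higher. The antiviral gene Mx1 was at least 251-fold higher. Ifit1, Ifit3 and Ifit2, interferon-induced proteins that block foreign RNA, were 229-fold, 149-fold and 123-fold higher. The receptor for formylated peptides Fpr2 was 200-fold higher, and the chemokines Ccl7 and Cxcl1 were 149-fold and 142-fold higher. At the other end, Susd3 was 14-fold, Tmem273 10.7-fold and the stress gene Gadd45g 9.29-fold lower. Tst, a mitochondrial sulfurtransferase, was 8.3-fold lower, the circadian factor Dbp 8.05-fold and Tsc22d3, a glucocorticoid-induced regulator, 7.95-fold. The cannabinoid receptor Cnr2 and the checkpoint kinase Chek2 were at least 9.12-fold and at least 7.37-fold lower. Tmem158 and Gask1b were 8.2-fold and 7.88-fold lower. Folds over readings near background depend on the floor: with it at each array's median the log2 difference was 9.42 in place of 10.87 for Il1b, 7.51 in place of 8.77 for Il6 and 5.86 in place of 7.97 for Mx1, also smaller for Cxcl10, Ifit1 and Ifit2, and Cnr2, Chek2 and Tmem158 were less than 2-fold lower.

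In the fixed lists, limma called a mean LPS rise over 2 pairs for nearly all cytokine and interferon-stimulated genes. The share that rose was smaller among early response genes and Toll-like receptor components. Of 23 cytokines and chemokines, 21 rose and 2 did not pass, and 22 rose when adjusted over the list alone. Tnf, the early macrophage cytokine, rose by 6.87 on the log2 scale (SE 0.28, adjusted p = 5.8e-13, higher in 2 of 2 pairs). Of 36 interferon-stimulated genes, 35 rose and 1 did not pass; adjusted over the list alone, 36 rose. Of 24 inflammatory enzymes and surface proteins, 21 rose and 3 did not pass, and adjusted over the list alone 23 rose and 1 fell. Among them Clec4e, a receptor for mycobacterial glycolipid, was 108-fold higher with LPS and the costimulatory receptor Cd40 104-fold. Nos2, the inducible nitric oxide synthase, was 2.06-fold higher, and 0.91 on the log2 scale after quantile normalization. Of 23 genes of the NF-kB and AP-1 early response, 16 rose, 1 fell and 6 did not pass; 17 rose and 1 fell when adjusted over the list alone. The signalling adaptor Traf1 was 23.5-fold higher and the feedback inhibitor Socs3 18.7-fold, while Jun, a subunit of AP-1, fell by 1.80 (SE 0.26, adjusted p = 3.63e-05). Toll-like receptor signalling components followed, with 11 of 22 rising, 0 falling and 11 rising when adjusted over the list alone. Tlr2, a receptor for bacterial lipopeptides, was 35.8-fold higher.

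Outside the inflammatory lists the share of genes that limma called for LPS varied from list to list. Of 13 genes of MHC class I antigen presentation 6 rose, 0 fell and 7 did not pass, and 8 rose adjusted over the list alone; the peptide transporter Tap1 was 7.31-fold higher. Of 21 apoptosis genes 10 rose and 1 fell, the same counts as adjusted over the list alone, among them Cflar, an inhibitor of death receptors, at 17.3-fold higher. Of 17 oxidative stress genes 6 rose and 2 fell, or 8 and 2 adjusted over the list alone; the superoxide dismutase Sod2 was 8.55-fold higher. Among 20 LXR target genes 0 rose and 3 fell, also when adjusted over the list alone, and these were Abcg1, Scd2 and Pparg. Pparg, a lipid-sensing nuclear receptor, fell by 2.91 (SE 0.29, adjusted p = 2.18e-07). Of 27 ribosomal protein genes limma called 0, also when adjusted over the list alone, with 1 at an unadjusted p under 0.05. Of 28 lysosomal genes 1 rose and 1 fell, of 23 oxidative phosphorylation genes 1 and 1, and of 8 deacetylases 0 and 1; adjusted over the list alone these were 1 and 0, 1 and 1, and 0 and 2. Of 5 core and linker histones H3f3b rose and H1f2 fell, or 2 and 1 adjusted over the list alone.

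Over all genes, 669 of 4790 measured were at least 2-fold higher with LPS and 290 lower, and limma found that 626 of 5080 rose and 361 fell. Quantile normalization changed these to 560 higher and 429 lower, and to 543 risen and 557 fallen, and moved the median of measured genes from 0.02 to -0.17 on the log2 scale.

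TSA + LPS against TSA shows the LPS response in cells given the inhibitor. Il1b was 1700-fold higher, Cxcl10 142-fold, the antiviral gene Rsad2 at least 134-fold, the chemokines Ccl7 and Ccl5 each 133-fold, Cxcl11 124-fold, Il6 118-fold and Tnf at least 114-fold. Mx1 was 55.8-fold higher, against at least 251-fold without TSA, and Fpr2 56.1-fold against 200-fold. The difference between the LPS responses was not tested. The median of the cytokine and chemokine list was 3.55 here and 4.10 without TSA, and that of interferon-stimulated genes 2.93 and 3.98. Early response genes went the other way, with a median of 1.78 here and 1.39 without TSA, Traf1 at 34-fold against 23.5-fold and Nfkbia at 17.5-fold against 13.4-fold. All these medians lay above the middle 95 percent of random lists. The early response list itself was lower with TSA at rest, with a median of -0.37 (percentile 0.21). It was not higher in TSA + LPS than in LPS either, at -0.27 (percentile 7.75), so a lower starting level enters its larger LPS response. By the size rule 440 of 4785 genes were higher and 305 lower.

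**Figure D1:**
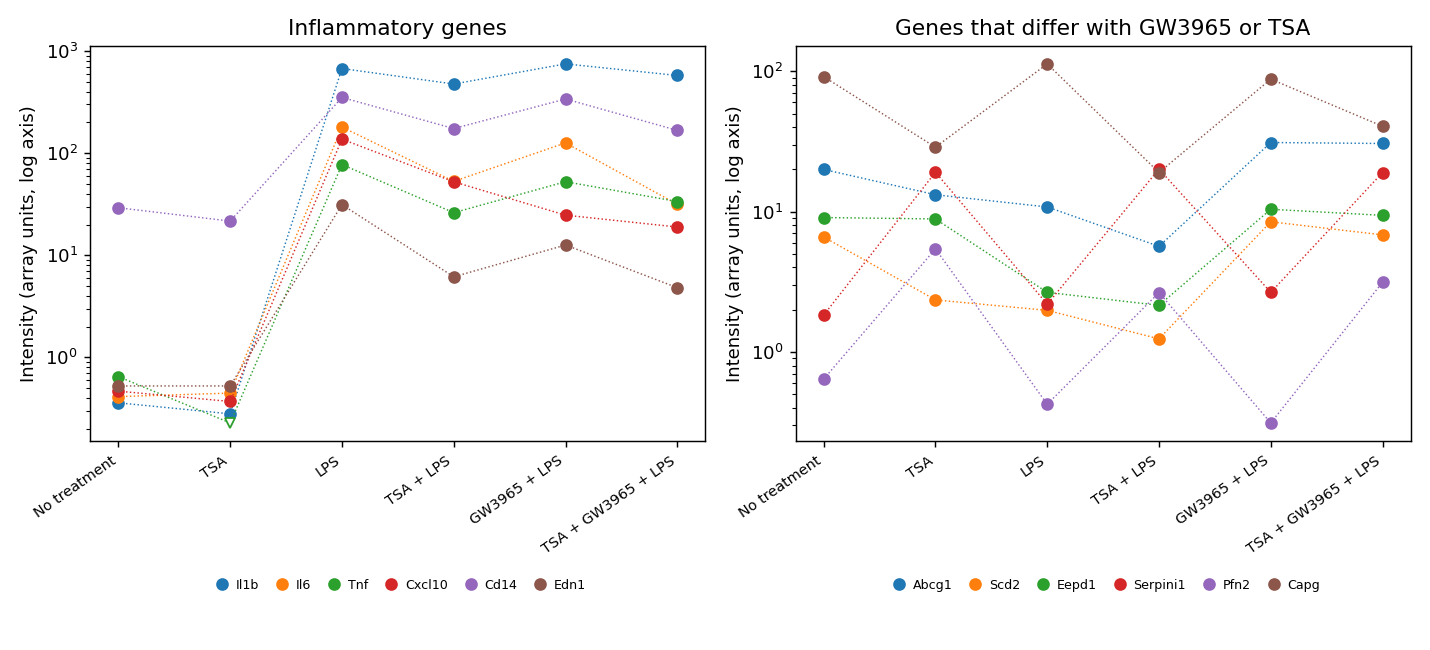
Intensity in array units on a log axis for 6 inflammatory genes (left) and 6 genes that differ with GW3965 or TSA (right) in the 6 groups, 1 array each; dotted lines only join the points of a gene, and the open triangle marks a value under the array's floor. Il6 stands at 180 with LPS and 52.9 with TSA + LPS, Abcg1 at 10.8 with LPS and 31.1 with GW3965 + LPS, and Serpini1 at 1.83 without treatment and 19.1 with TSA.

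TSA against No treatment gives the effect of the inhibitor on resting cells, and the mean over 3 pairs averages its effect over the backgrounds. Some of the genes highest with TSA were under the floor without it. Serpini1, a protease inhibitor best known from neurons, was higher by a mean of 3.14 ± 0.28 on the log2 scale (SD, n = 3 pairs), 8.82-fold. Pfn2, an actin-binding profilin, was higher by 3.02 ± 0.35 and Armcx2 by 2.60 ± 0.13. The lipid transfer protein Stard10 was under the floor on all arrays without TSA and was higher by at least 2.88 ± 0.08. Misp3 and Prtn3, a protease of neutrophil granules, were higher by at least 3.31 ± 0.59 and at least 3.12 ± 0.96. Insl6, Rsph9, a protein of the ciliary radial spoke, Bex3 and the zinc transporter Slc30a4 were higher by 2.39 ± 0.26, 2.31 ± 0.10, 2.29 ± 0.11 and 2.26 ± 0.39. Going down, the actin-capping protein Capg was lower by a mean log2 difference of -1.79 ± 0.74, Ubxn8 of -1.71 ± 0.43, and the focal adhesion protein Parvg of -1.67 ± 0.33. Mgll, a monoglyceride lipase, stood at -1.62 ± 0.42 and the fatty acid synthase Fasn at -1.43 ± 0.28. The tyrosine phosphatase Ptpn1 stood at -1.47 ± 0.35, the spermidine synthase Srm at -1.40 ± 0.19, Stra6l at -1.29 ± 0.03, Cmtm3 at -1.28 ± 0.35 and Atad3a at -1.22 ± 0.22. All 20 passed limma; with the floor at each array's median Prtn3, Parvg and Srm did not, nor did Fasn with its probes averaged.

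**Figure D2:**
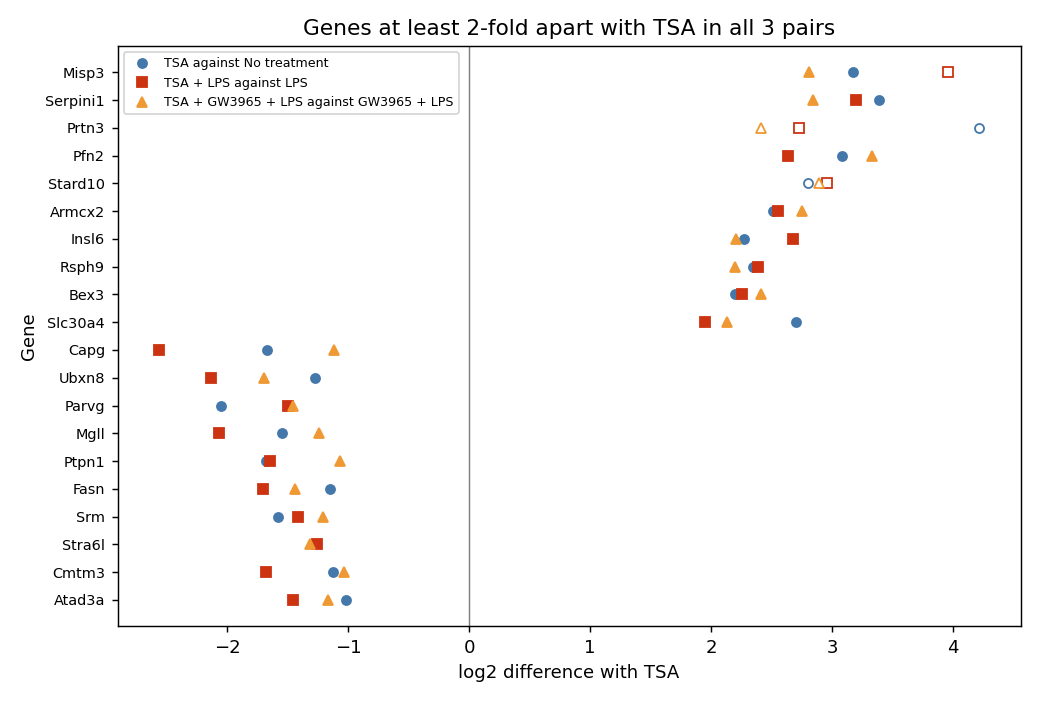
The log2 difference with TSA (horizontal axis) in each of the 3 pairs of arrays for the 10 genes highest and the 10 lowest among those at least 2-fold apart in all pairs; symbols give the pair, and open symbols are lower bounds. Serpini1 lies at 3.39, 3.20 and 2.84, and Capg at -1.67, -2.57 and -1.12.

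Some histone and deacetylase genes rose with TSA, and most members of these lists did not pass. Of 5 core and linker histone genes 2 rose, the linker histone H1f2 by 1.74 (SE 0.25, adjusted p = 0.000146, higher in 3 of 3 pairs) and the variant H2az1 2-fold (SE 0.19, adjusted p = 0.00154, 3 of 3 pairs); 0 fell, and adjusted over the list alone the counts were the same. Of 8 deacetylase genes 3 rose, also when adjusted over the list alone, namely Hdac5, Hdac6 and Sirt1, by 0.73, 0.77 and 0.83. Quantile normalization left 2 of them and the floor at each array's median 1. Of 24 genes known to respond to such inhibitors 3 rose and 2 fell, the same as adjusted over the list alone. The list sets no direction for its genes, so these counts do not show whether they moved in the known direction. The death receptor Fas rose by 1.46 (SE 0.23, adjusted p = 0.00028, 3 of 3 pairs), the metal-binding Mt2 by 1.30 and the transcription factor Klf4 by 0.67. Cdkn1a, the cell cycle inhibitor p21, fell by 1.04 (SE 0.21, adjusted p = 0.0025, 3 of 3 pairs), and Klf6 fell by 0.87. With the floor at each array's median Cdkn1a had a limma adjusted p of 0.064 (3e-04 to 0.064 over 8 settings). These 8 vary the scaling, floor, level filter and probes, not the prior variance, and leave out no pair. Fas also stands in the apoptosis list, in which 4 of 21 genes rose and 1 fell, the same as adjusted over the list alone; Pmaip1, Casp4 and Casp6 rose and Bak1 fell. With the floor at each array's median 1 histone gene, 2 inhibitor-responsive genes and 1 apoptosis gene rose, and none of these lists had a member that fell.

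Part of the antioxidant, lysosomal and lipid genes fell with TSA. Of 17 oxidative stress genes 7 fell and 3 rose, or 8 and 4 adjusted over the list alone. The heme oxygenase Hmox1 fell by 1.24 (SE 0.22, adjusted p = 0.000714), the glutathione synthesis enzymes Gclc and Gclm by 1.19 and 0.88, and the thioredoxin reductase Txnrd1 by 1.09. Of 28 lysosome and phagocytosis genes 6 fell and 0 rose, or 9 and 0 adjusted over the list alone, and the cathepsins Ctsk and Ctsz fell by 1.16 and 1.04. Of 20 LXR target genes 5 fell and 0 rose, also when adjusted over the list alone: Nr1h3, Apoe, Fasn, Scd2 and Rassf1. Nr1h3, which encodes an LXR itself, fell by 1.34 (SE 0.26, adjusted p = 0.00148). Of 10 genes of cholesterol synthesis and uptake 2 fell, Nsdhl and Sc5d, and 5 fell adjusted over the list alone. Of 24 heat shock and unfolded protein genes 3 rose and 5 fell, or 4 and 6 adjusted over the list alone; the small heat shock protein Hspb1 rose by 1.88 and the endoplasmic reticulum chaperone Hspa5 fell by 0.81. With the floor at each array's median 2 oxidative stress genes fell and 2 rose, and 2 lysosomal, 3 LXR target, 1 cholesterol and 1 heat shock gene fell.

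Of 23 oxidative phosphorylation genes 7 rose and 1 fell, the same as adjusted over the list alone, with 5 and 2 after cyclic loess and 2 and 0 with the floor at each array's median. The respiratory chain subunits Ndufv2 and Uqcrb rose by 0.92 and 0.93, and Atp5b, a subunit of the ATP synthase, fell by 1.06. Of 27 ribosomal protein genes 5 rose and 0 fell, and 9 rose adjusted over the list alone; after cyclic loess limma called 0 risen and 1 fallen, with 5 and 3 at an unadjusted p under 0.05. Among 13 housekeeping genes Pgk1 rose and Ywhaz, Gusb and Eef1a1 fell with TSA, or 2 and 3 adjusted over the list alone. Actb and Gapdh did not pass, with mean log2 differences of -0.11 and 0.43. Ywhaz and Gusb did not pass without the LPS pair, and with the floor at each array's median Pgk1 rose and 0 of the 13 fell.

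Without LPS, 330 of 4729 genes were at least 2-fold higher with TSA and 222 lower. Across the 3 pairs limma found that 557 of 5080 genes rose and 383 fell, and 87 genes were 2-fold higher and 10 lower in every pair. The balance was nearly even after quantile normalization (300 higher and 289 lower; 487 risen and 456 fallen) and after cyclic loess (266 and 262; 493 and 471). The total of 940 genes became 341 with the floor at each array's median, and 623 without the No treatment pair.

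TSA + LPS against LPS is the comparison that the series title is about, namely what the inhibitor does to inflammatory genes that LPS switches on. Many were lower with TSA, and others stayed level. Il6 was 3.4-fold lower with TSA + LPS than with LPS, Tnf 2.96-fold, Cxcl10 2.61-fold and Il1b 1.42-fold. Among strongly induced genes the largest drop was in Ptx3, a soluble pattern recognition protein, at 13.4-fold lower. Arhgef2 was 8.16-fold lower, the chitinase-like Chil1 7.25-fold, Vnn3 5.18-fold and the vasoconstrictor peptide gene Edn1 5.08-fold. The antiviral kinase Eif2ak2 was 6.71-fold lower, but 1.05-fold lower with TSA where GW3965 was present. Ptgs2, the inducible cyclooxygenase, was 3.93-fold lower, the interferon gene Ifng 3.87-fold, Tma16 3.76-fold and Tmem178 3.56-fold. Other induced genes stayed level: the cytokine Il18, the LPS-degrading Aoah, the interferon-inducible Ifi204, the purine enzyme Pnp, the NF-kB inhibitor Nfkbia and P2ry13, Six4, Nt5c3, Cep55 and Ms4a6d differed by at most 1.04-fold. Nfkbia stood at 198 with LPS and 191 with TSA + LPS.

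Of 669 genes at least 2-fold higher with LPS, 163 were at least 2-fold lower with TSA + LPS than with LPS. That is 24.4% (Clopper-Pearson 95% interval 21.2 to 27.8, for the counting of genes only), and the median difference was -0.53. A further 18 were 2-fold higher. Over all measured genes of this pair 458 of 4794 were at least 2-fold lower, so the lowering was not confined to LPS-induced genes. In simulated arrays with no effect of TSA on any gene, 2.21% of LPS-induced genes were lower. Part of this arises because the LPS array enters both the choice and the difference: with no shared array the simulation gave 1.24%. The simulation holds no variation shared by the genes of a sample, which 1 array per group cannot separate from an effect of TSA. Among 515 genes chosen instead in GW3965 + LPS, which shares no array with the difference, 19.6% were lower and the median was -0.39. Of the 669 genes, 358 (53.5%) were at least 2-fold higher in TSA + LPS than in TSA. In reverse, of 440 genes at least 2-fold higher in that pair, 341 (77.5%) were so in LPS against No treatment. These 2 counts apply no level filter in the second pair. With the filter in both pairs, 337 genes were higher in both. Genes chosen at a cut in 1 pair can fall short of it in another without any effect of TSA.

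By limma's mean over 3 pairs, 6 of 23 cytokines and chemokines fell with TSA, 0 rose and 17 did not pass. Adjusted over the list alone 7 fell. Only 12 of the 23 were measured in the pair without LPS. Tnf, under the floor with TSA alone, fell by 1.24 (SE 0.23, adjusted p = 0.0011, lower in 3 of 3 pairs), Il6 by 1.22 (SE 0.30, adjusted p = 0.009, lower in 2 of 3), and Il12a, Il1a, Edn1 and Ccl22 by 1.23, 0.89, 1.24 and 0.70. Il1b did not pass, with a mean of -0.41 (SE 0.20, adjusted p = 0.15, lower in 3 of 3 pairs). It passed under quantile normalization (adjusted p = 0.045, with 0.045 to 0.32 over the same 8 settings as for Cdkn1a) and cyclic loess. Ptgs2 and Nos2 did not pass either, at -0.60 and -0.23. Of 24 inflammatory enzymes and surface proteins 4 rose and 4 fell, or 4 and 5 adjusted over the list alone. The collagenase Mmp13, the arginase Arg2, Cd80 and Serpinb2 rose, and the membrane protease Mmp14, the urokinase receptor Plaur, the cationic amino acid carrier Slc7a2 and Clec4d fell. Of 23 early response genes 5 fell, namely Nfkb2, Tnip1, Zfp36, Socs1 and Atf3, 0 rose, and 7 fell adjusted over the list alone. Of 22 Toll-like receptor signalling components 5 fell, 0 rose and 7 fell adjusted over the list alone; the LPS co-receptor Cd14 fell by 0.83, the adaptor Myd88 by 0.96 and the kinase Irak1 by 1.02, with Ikbkg and Tnfrsf1a. Of 13 genes of MHC class I presentation 4 fell, also when adjusted over the list alone, namely Tap1, Psmb10, Psme1 and Psme2, and 1 fell without the LPS pair.

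Interferon-stimulated genes did not move together. Cxcl9, Cxcl11, Ifi47 and Tgtp1 rose and Irf8, Cxcl10 and Ccrl2 fell, 4 and 3 of 36, the same as adjusted over the list alone; without the LPS pair 10 rose and 0 fell. The T cell attractant Cxcl11 rose by 1.18 (SE 0.28, adjusted p = 0.0067), and Cxcl10 fell by 0.70 (SE 0.23, adjusted p = 0.043, lower in 3 of 3 pairs).

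In this pair 363 of 4794 genes were higher and 458 lower. Gapdh was 1.99-fold higher, with a log2 difference of 0.50 under quantile normalization. Actb was higher by 0.24 and turned to -0.21 under quantile normalization. With the floor at each array's median limma called 0 cytokines, although 8 fell at an unadjusted p under 0.05. The adjusted p of Tnf was then 0.15 (6.9e-07 to 0.15 over the same 8 settings), that of Il6 0.077 (4.8e-07 to 0.077) and that of Cxcl10 0.21 (0.013 to 0.21). The same floor left 0 early response genes (7 at an unadjusted p under 0.05), 0 MHC class I genes (5), 0 interferon-stimulated genes (4 up and 5 down) and 2 Toll-like receptor components. Leaving out the LPS pair left 4 cytokines, namely Tnf, Il6, Il12a and Edn1.

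**Figure D3:**
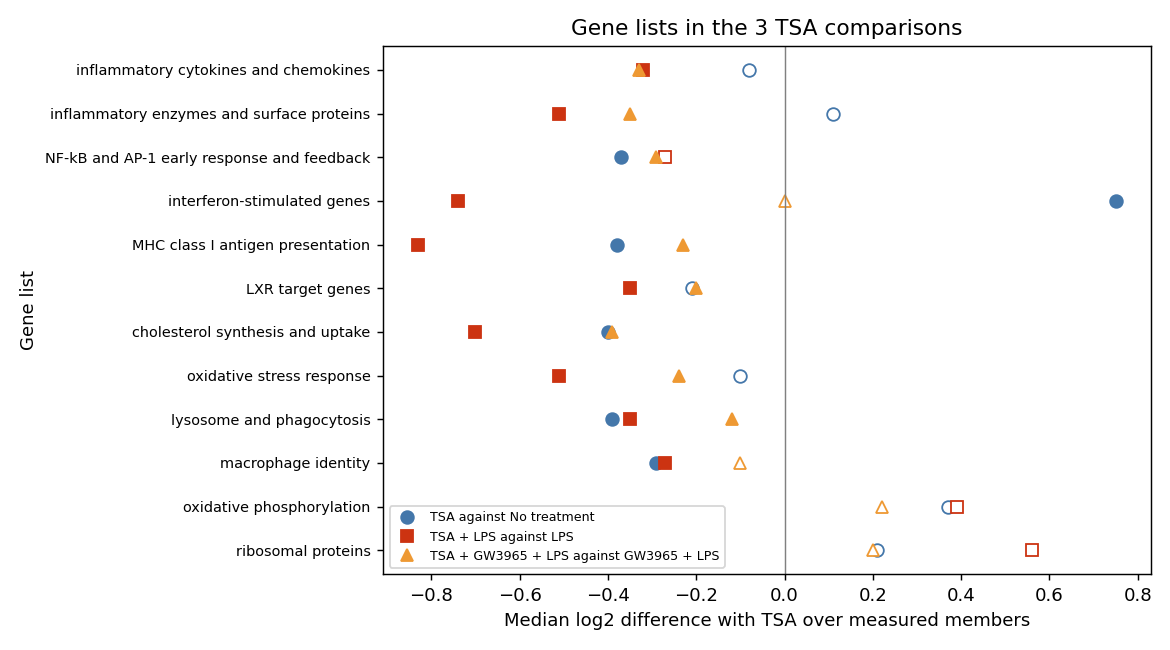
Median log2 difference with TSA (horizontal axis) over the measured members of 12 gene lists in the 3 TSA pairs; filled symbols lie outside the middle 95 percent of level-matched random lists. Interferon-stimulated genes lie at 0.75 without LPS, -0.74 with LPS and 0.00 with GW3965 and LPS (24, 36 and 35 measured members). Cytokines and chemokines lie at -0.08, -0.32 and -0.33 (12, 23 and 23 measured members).

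TSA + GW3965 + LPS against GW3965 + LPS repeats the question with the LXR agonist present. Il6 was again lower with TSA, by 4-fold, and the colony-stimulating factor gene Csf2 3.27-fold, Il12a 2.91-fold and Edn1 2.62-fold. Ptx3 was 8.32-fold and Arhgef2 6.78-fold lower. The glutathione enzymes Gclc and Gclm were 2.95-fold and 2.77-fold lower. Mmp13 was 5.28-fold and Hspb1 3.96-fold higher. The cytokine and chemokine median was -0.33 (percentile 0.03), next to -0.32 (percentile 1.62) without GW3965. Over the 669 LPS-induced genes, though, 3.89% (2.55 to 5.64) were 2-fold lower, the median was -0.08, and 25 were higher; simulation with no effect gave 1.24%. Over all genes 227 of 4697 were higher and 53 lower.

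The TSA differences resembled each other in the 3 pairs, which share no array. Correlations across genes, which are not independent replicates, were 0.58, 0.61 and 0.60, and 89.4% to 91.8% of genes 2-fold apart in a pair had the same sign in another. The LPS responses without and with TSA correlated at 0.81.

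GW3965 + LPS against LPS, and the same with TSA, show what the LXR agonist did to stimulated macrophages. The test called few genes, among them a pair of lipid genes that rose and a chemokine that fell. Scd2, a fatty acid desaturase, rose by a mean of 2.28 on the log2 scale, 4.86-fold (SE 0.29, adjusted p = 0.00066, 2 of 2 pairs). Abcg1, a cholesterol exporter, rose by 1.98, 3.96-fold (SE 0.27, adjusted p = 0.0011, 2 of 2 pairs), from 10.8 to 31.1 without TSA and from 5.66 to 30.6 with it. Eepd1 rose by 2.05 (SE 0.26, adjusted p = 0.00066, 2 of 2 pairs), and Cxcl10 fell by 1.97 (SE 0.29, adjusted p = 0.0019, 2 of 2 pairs). These were all the genes that limma called for GW3965; 140 of 5080 had an unadjusted p under 0.05.

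Other genes differed at least 1.5-fold in both pairs without passing the test. Cfap126 was 3.12-fold higher on average, Fasn 2.54-fold, the acyl-CoA synthetase Acsl3 2.21-fold, the asparagine synthetase Asns 2.16-fold, the isocitrate dehydrogenase Idh1 2.12-fold, the stress factor Ddit3 2.09-fold and Tmem86a 2.05-fold. Lower were Ch25h, which makes an oxysterol, 3.16-fold, the chemokines Cxcl11 2.91-fold and Ccl12 2.07-fold, Lhx4 2.43-fold, Isg20 2.13-fold, the feedback inhibitor Socs1 2.13-fold, Tgtp1 2.12-fold, Ccnd2 2.08-fold and Mov10 1.98-fold. Among 20 LXR target genes Abcg1 and Scd2 rose and 3 rose adjusted over the list alone. The list's median was 0.14 without TSA (percentile 95.04) and 0.35 with it (percentile 99.89). Abca1 and Srebf1, other LXR targets, did not reach the level filter, nor did the anti-inflammatory cytokine gene Il10; Abca1 read 0.276 with LPS and 0.416 with GW3965 + LPS.

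Interferon-stimulated genes were lower with GW3965 and LPS than with LPS, with a median of -0.81 (percentile 0.00) and 9 of 35 at least 2-fold lower, but at -0.10 (percentile 5.83) with TSA; 1 of 36 fell by limma, Cxcl10, and 6 fell adjusted over the list alone. Cytokines and chemokines had medians of -0.23 and -0.31 (percentiles 0.34 and 0.02), with 0 of 23 past limma, 5 at an unadjusted p under 0.05 and 2 fallen adjusted over the list alone. No other list had a member past limma for GW3965; adjusted over the list alone 2 heat shock and unfolded protein genes rose (6 at an unadjusted p under 0.05), 1 inflammatory enzyme or surface protein gene rose and 1 fell, and 1 early response gene fell. Of the 669 LPS-induced genes 7.03% (5.21 to 9.23) were 2-fold lower with GW3965 without TSA, with a median of -0.35, and 1.64% (0.824 to 2.92) with TSA, with a median of 0.11. Simulated arrays with no effect of GW3965 gave 1.97% and -0.12 for the former, which shares the LPS array with the choice of genes, and 0.908% (highest 1.68%) for the latter. Over 515 genes chosen in GW3965 + LPS the median without TSA was -0.17. Over 440 chosen in TSA + LPS against TSA, which shares no array with it, the median was -0.22. For each gene, the gap between the 2 GW3965 differences equals that between the TSA differences with LPS alone and with GW3965 and LPS. Both come from the same arrays, so for interferon-stimulated and LPS-induced genes these gaps are 1 result, not 2. Over all genes 22 of 4622 were higher and 58 lower without TSA, and 82 of 4682 higher and 27 lower with it. Simulated arrays with no effect gave 57 to 94 such genes in all for the pair without TSA and 56 to 86 for the pair with TSA. The GW3965 differences of the pairs correlated at -0.13 across genes, and with the floor at each array's median limma called 0 genes, with 128 at an unadjusted p under 0.05.

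Markers of other cells that such a preparation can hold were also tested. Of 7 neutrophil markers S100a8, Prtn3 and Stfa3 rose with TSA and Csf3r fell; with LPS S100a8, Camp and Stfa3 rose and Ltf fell; adjusted over the list alone 3 rose and 2 fell for either. The neutrophil list's median with TSA was 0.53 without LPS, 0.86 with LPS and 0.53 with GW3965 and LPS (percentiles 87.46, 99.07 and 94.68), and with the floor at each array's median limma called 0 of these markers for TSA, with 4 at an unadjusted p under 0.05. Of 4 dendritic cell markers the actin-bundling Fscn1 and Cd83 rose with LPS, and Fscn1 fell with TSA, the same as adjusted over the list alone. That fall of Fscn1 did not pass without the LPS pair, nor with the floor at each array's median. Of 6 mesothelial and fibroblast markers Krt19 fell with LPS, also adjusted over the list alone, and limma called 0 for TSA, with 0 at an unadjusted p under 0.05. Among 5 B cell, 5 T and NK cell and 5 eosinophil and mast cell markers limma called 0 for any treatment, also adjusted over the list alone, with at most 2 per list at an unadjusted p under 0.05. Of 28 macrophage identity genes 3 fell with TSA, also adjusted over the list alone, namely the integrin Itgax, the beta-glucan receptor Clec7a and Cd14, and 0 rose; 6 fell after quantile normalization, 7 after cyclic loess and 5 without the LPS pair. That list's median with TSA was -0.29 without LPS, -0.27 with LPS and -0.10 with GW3965 and LPS (percentiles 0.15, 1.28 and 5.11).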

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

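The tests of the LPS-induced genes by the strength of TSA and by GW3965, all tests of the interferon-stimulated genes and the test of low resting level were chosen only after the result was seen.

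LPS-induced genes were lowered more by TSA with LPS alone (median -0.53) than with GW3965 and LPS (median -0.08). For each gene this gap equals that between the GW3965 differences without and with TSA, so the latter is no separate evidence. Picking the genes on the LPS array is argued against as the whole cause. Genes picked in GW3965 + LPS still had a median of -0.39 with LPS alone, against -0.14 with GW3965 and LPS. That gap is smaller, so the choice may be part of the cause, although the -0.14 shares the GW3965 + LPS array with the choice. A distortion of the TSA + LPS array that moves genes of like level alike is argued against too. Induced genes lay -0.40 from level-matched genes in the difference between the pairs (percentile 0.00). A weaker raising action of TSA in the TSA + GW3965 + LPS sample is also argued against. For 149 genes raised by TSA at rest and unresponsive to LPS the mean differences stood in a ratio of 0.969 (bootstrap over genes 0.898 to 1.05). A weaker lowering action was not tested: over all genes 458 were at least 2-fold lower with TSA in the LPS pair and 53 in the GW3965 + LPS pair. A candidate explanation that stays open is that GW3965 had already lowered the same genes: 440 genes chosen in TSA + LPS against TSA had a median of -0.22 (bootstrap -0.29 to -0.19) with GW3965. It cannot be told apart from a property of the single LPS or GW3965 + LPS sample, because both arrays enter the pattern as well as this contrast (other properties of the single TSA + LPS sample were not tested), so the value partly restates the pattern; a stronger LPS response throughout would also shift the 305 genes lower with LPS in TSA-treated cells upward, and their median was only 0.05.

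Interferon-stimulated genes were higher with TSA alone (median 0.75, 24 measured members) and lower with TSA and LPS (median -0.74, 36 measured members) than without it. The difference between these medians was not tested, and the change of members can be part of it. The list's percentile of 0.00 among matched lists cannot exclude a distortion of the TSA + LPS array that moves genes of like level alike. That percentile itself served to flag the pattern, so the outcome was fixed in advance. With matching on the TSA and No treatment arrays instead, 0.00 percent of lists had a higher median than the list with TSA alone. That median also served to flag the pattern, so this is only weak evidence against an effect of low level and of the level filter. Of 21 members at or above the median of the No treatment array, 14 were higher with TSA, and the median difference of the 21 was 0.71. Against a reversal by any LPS background stands the median of 0.00 with GW3965 and LPS. A biological dependence on LPS without GW3965, or a property of the single LPS or TSA + LPS sample, may each account for the pattern and were not separated.

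Genes raised by TSA in all 3 pairs were often dim at rest, 28.7% of 87 lying under the No treatment median against 11.5% of level-matched draws. Room to rise at low level cannot be told apart from this, because matching on the mean of all arrays by itself would give 39.1%. No biological explanation was tested.

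Of the 10 ways to split the 6 arrays into 3 and 3, only 1, the real split by TSA, gave as many as 940 genes, and the highest other gave 0. With 10 splits a share under 0.05 cannot be reached. The other splits also leave the TSA difference in the residual, which lowers their counts, so the 0 is no measure of chance. Lysosome and phagocytosis genes were lower with GW3965 and LPS (median -0.12) and higher with GW3965, TSA and LPS (median 0.41), a difference that was not tested. Probes with no gene symbol, used in no comparison, also differed: of 548 measured, 64 were at least 2-fold higher and 34 lower with LPS, and 7 were higher and 1 lower with TSA in all 3 pairs.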

How the results depend on the processing

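The matching of random lists on the compared arrays and the counts of list members under other settings were chosen only after the result was seen. No paired analysis was possible because each group has 1 array and the labels carry no replicate numbers; the pairs used are arrays matched by treatment. Of 132 recomputed answers, 103 stayed within 1.5 times, their interval or their spread and 29 did not. Of named gene values and list medians past their threshold 0 changed sign, which was not counted for values short of it; single-pair gene values lost the size rule 28 times and gained it 5 times, list medians left the outer range 7 times and entered it 17 times, and adjusted p-values of the TSA effect lost the threshold 8 times and gained it 2 times. Counts of list members past limma stayed within 1.5 times 90 times and did not 34 times. In the order LPS, TSA, TSA with LPS, LPS with TSA, GW3965 with LPS, TSA with GW3965 and LPS, and GW3965 with TSA and LPS, the size counts were 579, 289, 454, 427, 49, 136 and 55 with the level filter at the 75th percentile (fewer genes measured), and 1803, 1559, 1941, 1715, 463, 997 and 788 at 1.5-fold. No level filter gave 186 for the last. Shares of LPS-induced genes lower at 1.5-fold were 41.2% with TSA, 11.9% with TSA and GW3965, 20.8% with GW3965 and 4.69% with GW3965 and TSA; for genes chosen in GW3965 + LPS they were 19.6% with TSA and 4.85% with GW3965. limma called 341, 650 and 0 genes for TSA, LPS and GW3965 with the floor at the median (128 for GW3965 at an unadjusted p under 0.05), 613 and 632 for TSA and LPS with the filter at the 75th percentile (fewer genes tested), 20 for GW3965 without the filter, and 623 for TSA without the No treatment pair (fewer arrays). The median correlation of the TSA responses was 0.48 without the filter. Except where fewer genes or arrays or a lower threshold explain it, the cause was not tested. Removing the floor cannot alter the size counts, since each floor lies under the level the brighter array must reach by more than 2-fold. Quantile normalization gave 68 list medians outside the middle 95 percent, loess 66, probe averaging 68 and matching on the compared arrays 64. Low signal limits genes near the floor, for which only bounds exist.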

Other observations

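Except for the calls under other settings, no test in this part was chosen only after the result was seen. The part gives values of lists fixed beforehand. Of 19 cell cycle genes, Mki67 and Ube2c rose with LPS and Cdk4, Cdc6, Mcm3 and E2f1 fell, also adjusted over the list alone, and with TSA the mitotic kinase Cdk1 rose by 1.26 (SE 0.21, adjusted p = 0.000534, 3 of 3 pairs) and Foxm1 fell. Of 12 alternative activation genes 3 rose with LPS, Ccl17, Ccl22 and Socs2, and 4 adjusted over the list alone. With TSA Retnla and Klf4 rose and the chemokines Ccl24 and Ccl22 fell, also when adjusted over the list alone. The fall of Ccl22 did not pass without the LPS pair, and with the floor at each array's median only Retnla rose and 0 fell. Of 17 glycolysis genes Pfkp and Hif1a rose and Pfkm and Tpi1 fell with LPS, or 3 and 3 adjusted over the list alone. With TSA Pgk1 and the lactate carrier Slc16a3 rose and Pfkl and Aldoa fell, or 2 and 3 adjusted over the list alone. Pfkl and Aldoa did not pass without the LPS pair, and with the floor at each array's median only Pgk1 rose and 0 fell. Of 10 MHC class II genes H2-Oa rose with LPS and the invariant chain Cd74 fell with TSA, by 0.73 (SE 0.20, adjusted p = 0.0171), also adjusted over the list alone.

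Of 13 nuclear receptors and cofactors Rxrg and Pparg fell with LPS, and Nr1h3 and the corepressor subunit Gps2 fell with TSA, the same as adjusted over the list alone. Of 4 neuronal and synaptic genes limma called 0 for any treatment, also adjusted over the list alone, with 1 at an unadjusted p under 0.05 for TSA; 26 were on the array and most were too dim. Il12b, Ifnb1 and H1f0 have no named probe. Parp14, an interferon-stimulated gene, was at least 32-fold lower with TSA + LPS than with LPS but 6.08-fold higher with TSA when GW3965 was present, and did not pass limma.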
